A study of Mus musculus with 32 samples.

How the data were processed

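RNA sequencing libraries were analysed from mouse growing oocytes at postnatal day 14, MII oocytes, 2-cell and 4-cell embryos and AB2.2 embryonic stem cells, 32 samples in 16 groups of 2. Per the labels' protocols, oocyte and embryo libraries were made with Smart-seq2, a full-length cDNA method for few cells, and stem cell libraries with a TruSeq poly(A) kit. The authors deposited 1 table of read counts per sample, not normalized, with 55335 genes and 1153 repeat subfamilies (680 LTR, 204 DNA, 158 LINE and 35 SINE subfamilies among them). Per the submitters' processing notes, the tools included cutadapt 1.16 and STAR, and the build was mm10. The counter, its annotation, the use of strand and the treatment of reads with several positions are not given in the sources used here. Values of genes with near-identical copies (Zscan4, Tdpoz, Usp17l, Pramef and Obox families, histones, ribosomal proteins and their retrocopies such as Rpl37 and Rpl37rt) are therefore uncertain, as are those of overlapping or antisense genes and of genes that hold repeats. Of the gene identifiers, 55154 matched the GENCODE annotation of the same build without their version number and 54587 with it; symbols and positions come from that match.

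Samples were grouped by their labels, and 13 comparisons, 6 differences between comparisons and 7 differences between drugs were made. Growing oocytes, MII oocytes, stem cells, 2-cell embryos and 4-cell embryos were each fitted alone, so that groups of a stage share 1 estimate of the spread. Comparisons between stages used the MII oocytes, both untreated or vehicle 2-cell groups and the vehicle 4-cell group, and the differences used the 18 embryo libraries, these 10 stage libraries, or the 14 stem cell and 2-cell libraries without the 12-month embryos. Each fit used edgeR 4.0.16 in R 4.3.3: low counts were removed with filterByExpr by group (minimum count 10, minimum total 15), libraries scaled by TMM over genes and repeats together, dispersions estimated robustly and groups tested with the quasi-likelihood F-test. The Benjamini-Hochberg adjustment ran over genes and, separately, over repeat subfamilies, with a threshold of 0.05. Where both libraries of a group held 0 counts, a bound was computed from 3 counts over the group; it covers counting error only, since reads without molecular identifiers are not independent molecules. The stem cell kit differs from that of the embryos and the 12-month embryos lack the vehicle, so neither kit nor vehicle can be separated from system or age.

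The tests, 24 gene lists (4 of them markers of other cells) and the rule for named genes were set before the data were examined. Lists with at least 5 tested members were tested with camera in edgeR and limma 3.58.1 at a preset correlation of 0.01, beside camera with an estimated correlation and fry, with adjustment over lists within a comparison. Over the 13 comparisons the preset test called 112 pairs of list and comparison, and the estimated correlation 3 (the 2-cell-stage genes with cycloheximide in stem cells and with aphidicolin and MG132 at 2 cells, both not with the replicate block). List members were also counted with p values adjusted over the list alone. The rule named, per comparison, the 5 largest increases and 5 largest decreases among called genes with at least 10 CPM in the higher group, no overlap between the libraries of the groups and a symbol that is not a predicted model; up to 4 called members of each list that camera called or that had at least 25% of its tested members called; a fixed set of index genes and subfamilies; and 3 called subfamilies per direction. The text gives mainly those that kept their call when any 1 library was left out, and says where not; genes with 1 to 3 counts in a group are left out. Members of counts of 5 or fewer are named whatever the rule and were chosen after their values were seen. A list of 44 interferon-stimulated genes was also written after the values were seen.

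Zygotic and maternal sets came from an edgeR fit of the 12-month oocytes and embryos (4-fold, with 2-fold and 8-fold as alternatives). For comparisons with a common vehicle group, 10 pairs of unchanged groups and their vehicle libraries were simulated. The overlap of independent lists was computed as the product of both counts over the genes tested. Neighbouring genes were counted against 10000 random sets of like expression. Same-numbered libraries of the 2-cell drug and vehicle groups deviated together, with correlations of 0.202 to 0.402 across 9053 genes over their 6 pairs, so their numbers are taken to pair them; this pairing comes from the data, since no label gives a shared day or batch, and the 12-month embryos stand outside it (-0.0316 to 0.0612). The block was fitted over all 5 groups at 2 cells. The alternatives were DESeq2 size factors, the DESeq2 1.42.0 Wald test, no low-count filter, a filter of 5 CPM in 2 libraries, a replicate block, library sizes from genes only, a fit of the compared groups alone, a 2-fold minimum and leaving out each library. Tables were joined and drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

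The fits were tested on simulated data, with counts drawn from the real means and library sizes and 200 genes changed by 2-, 4- or 16-fold; the low-count filter was applied to the simulated counts. In growing oocytes (15386 genes simulated) 49.3% of 2-fold and 98.5% of 4-fold changes were called, and in stem cells with cycloheximide (18696 genes) 82.1% and 98.5%. In MII oocytes (15083 genes) the values were 1.49% and 44.8%. For cycloheximide at 2 cells (22391 genes) 17.9% of 4-fold and 75.8% of 16-fold changes were called, and at 4 cells (22520 genes) 8.96% and 63.6%. Of the simulated calls in growing oocytes 6 of 171 were of unchanged genes, and of those in stem cells with cycloheximide 20 of 206. No 2 libraries of a group differed by less than sampling noise (chi-square over degrees of freedom 2.52 to 253), and no sample was left out.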

Results

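RNA was measured in mouse growing oocytes, metaphase II (MII) oocytes, 2-cell (2C) and 4-cell (4C) embryos and the embryonic stem cell (ESC) line AB2.2. The 32 libraries form 16 groups of 2 replicates (rep). Growing oocytes came from ovaries at postnatal day 14 and carried a transgene for histone H3.3, either unaltered (H3.3WT) or with methionine in place of lysine 4 (H3.3K4M), a form that interferes with methylation of that lysine. MII oocytes came from females of 8 weeks (8w) or 12 months (12m). Untreated 2-cell embryos came from 12-month females, and the other embryos from females of 6 to 8 weeks, cultured with aphidicolin (APH, an inhibitor of replicative DNA polymerases), cycloheximide (CHX, an inhibitor of translation), MG132 (a proteasome inhibitor) or the vehicle DMSO. Stem cells received cycloheximide, MG132 or DMSO. Total counts per library were lowest in 2-cell aphidicolin rep 1 (14313718) and highest in 4-cell aphidicolin rep 2 (34713159). Repeat subfamilies took 4.63% to 6.86% of the counts in MII oocytes, 19.9% and 20.8% in vehicle 2-cell embryos, and 2.93% to 4.03% in stem cells. Below, levels are means ± SD in CPM, counts scaled to a common library total, over n = 2 libraries per group, log2 fold changes carry their standard error, and adjusted p values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. A gene is called higher or lower at an adjusted p under 0.05. Camera p values of gene lists are adjusted over the lists of a comparison. No spike-in is stated, so each change is relative to the rest of its library. No label ties a library to its own culture or animals, so p values measure only the spread between these samples, which may be technical.

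The passage from MII oocyte to 2-cell embryo was compared between oocytes of 8-week females and vehicle 2-cell embryos. Many maternal transcripts fell: Mos, the kinase that holds the MII arrest, changed by -6.80 ± 0.47 on the log2 scale, the homeobox gene Obox2 by -6.70, the oocyte linker histone H1foo by -5.34, the spindle checkpoint kinase Bub1b by -6.23, and Plat, tissue plasminogen activator, by -5.47 (edgeR adjusted p at most 6.1e-05). Most genes known for a burst of expression at the 2-cell stage rose, such as Zscan4d, a zinc-finger gene of the telomere-linked Zscan4 cluster (7.51 ± 0.93), Zfp352 (10.66) and, from 0 counts in the oocytes, Zscan4b (at least 412-fold higher), Usp17la (at least 991-fold) and the initiation-factor-like gene BB287469 (at least 1997-fold). These bounds, like all bounds given here, set a group at 0 to 3 counts over the group and cover counting error only. In all, 4641 of 22954 genes differed (2317 higher and 2324 lower). Of the 2-cell-stage transient genes, 38 of the 47 tested were higher and 3 (Cwc15, AU022751 and Rnf114) lower (39 higher and 4 lower with p adjusted over the list alone). Camera gave p = 2.6e-21, and 0.0571 with an estimated correlation. Among the oocyte and maternal-effect genes, 39 of the 69 tested were lower and 2 (Ybx2 and Dnmt3l) higher (4 higher and 44 lower over the list alone). Camera gave p = 1.2e-15, and 0.0540 with an estimated correlation. Many mitosis and spindle genes fell too, including the kinase gene Aurkc (-4.17): 27 of the 47 tested were lower and 3 (Cdc25c, Cdc25b and Top2a) higher (5 higher and 28 lower over the list alone). Camera gave p = 5.2e-09, and 0.0540 with an estimated correlation. Without 2-cell DMSO rep 1 the count was 2811. With library sizes taken from genes only the split became 2794 higher and 1697 lower, and the median of all genes shifted by 0.28. Rnf114 lost its call without either 2C DMSO replicate, and with gene-only library sizes. AU022751 lost its call without either 2C DMSO replicate or MII 8w rep 2, and with gene-only library sizes. Cwc15 lost its call without either 2C DMSO replicate or MII 8w rep 2. Ybx2 lost its call without 2C DMSO rep 2 or either MII 8w replicate. Top2a lost its call without 2C DMSO rep 2 or MII 8w rep 2. Dnmt3l lost its call without MII 8w rep 1. With only the 4 libraries compared, AU022751, Cwc15, Rnf114 and Top2a lost theirs too.

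Many repeats rose at the same step. MERVL-int, the internal part of an endogenous retrovirus whose LTR MT2_Mm drives 2-cell genes, went from 46.2 ± 20.8 CPM in 8-week oocytes to 14083 ± 4747 CPM in vehicle 2-cell embryos (8.25 ± 0.46, edgeR adjusted p = 2.2e-06), in the normalisation of the fit across stages, and MT2_Mm rose by 5.76. The young LINE subfamilies L1Md_Gf (6.58) and L1Md_T (3.38), IAPEz-int (1.88) and the SINE B1_Mm (1.61) were also higher. By class, 182 of 604 LTR, 55 of 149 LINE and 25 of 35 SINE subfamilies were higher, against 19, 3 and 2 lower.

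**Figure D1:**
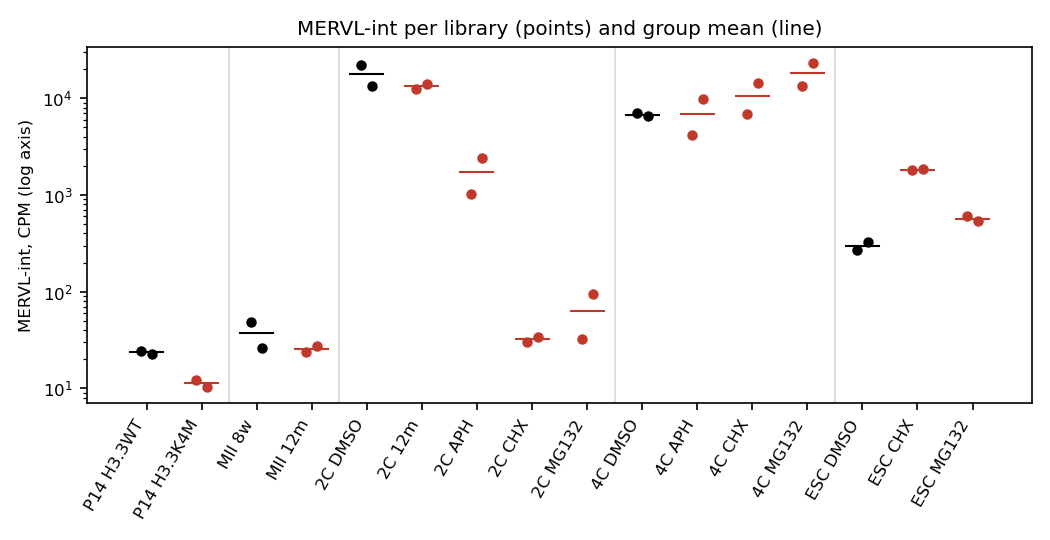
MERVL-int in each of the 32 libraries, as CPM scaled per stage fit on a log axis, by group (16, other axis). Points are libraries and lines group means. Vehicle 2-cell embryos lie at 13547 and 22121 CPM, 2-cell embryos with cycloheximide at 30.2 and 34.1 CPM, and stem cells with cycloheximide at 1804 and 1861 CPM against 268 and 330.0 CPM with vehicle.

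From vehicle 2-cell to vehicle 4-cell embryos, most ribosomal proteins, ribosome biogenesis genes and oxidative phosphorylation genes rose, and most oocyte and 2-cell-stage genes fell. The ribosomal proteins Rps27 (9.07) and Rpl38 (8.00 ± 0.53), the proteasome subunit Psmb5 (7.42), the respiratory-chain gene Cox7c (6.76), the trophectoderm regulator Tead4 (6.29) and the pluripotency-associated Dppa5a (6.28) were higher. Zar1, a maternal-effect gene, and the oocyte transcription factor Tbpl2 were at 0 counts at the 4-cell stage (at least 249-fold and at least 497-fold lower), and lower were Obox1 (-8.38), Zscan4d (-5.45) and Zfp352 (-4.13, edgeR adjusted p at most 0.000424 for these genes). The fit called 11237 of 22954 genes, 4498 higher and 6739 lower, around a median over all genes of -0.57. DESeq2 size factors shifted that median by 0.21 and gene-only library sizes by -0.15. Among cytosolic ribosomal proteins, 79 of the 79 tested were higher (79 higher and 0 lower over the list alone). Camera gave p = 1.4e-48, and 0.0632 with an estimated correlation. For ribosome biogenesis, 59 of the 60 tested were higher (59 higher and 0 lower over the list alone). Camera gave p = 4.8e-24, and 0.0632 with an estimated correlation. For oxidative phosphorylation, 64 of the 76 tested were higher and 3 (Sdha, Sdhc and Ndufa10) lower (65 higher and 3 lower over the list alone). Camera gave p = 7.5e-18, and 0.0632 with an estimated correlation. Of the oocyte and maternal-effect genes, 57 of the 69 tested were lower and 5 (Trim28, Taf4b, Zp3, Dppa3 and Ccnb3) higher (5 higher and 58 lower over the list alone). Camera gave p = 6.0e-18, and 0.0632 with an estimated correlation. Of the 2-cell-stage transient genes, 32 of the 47 tested were lower and 5 (Pramel7, Eif1a, Obox6, Pramel6 and Sp110) higher (5 higher and 32 lower over the list alone). Camera gave p = 0.000549, and 0.285 with an estimated correlation. MERVL-int was lower (-1.28), while RLTR45-int (5.72), MT2C_Mm (5.01), B2_Mm2 (2.07) and B1_Mm (2.04) rose and the oocyte-active LTR MTA_Mm fell (-2.81); 58 LTR subfamilies were higher and 111 lower. Over all classes 74 subfamilies were higher and 198 lower, and with DESeq2 size factors 80 and 134. MERVL-int lost its call without 2C DMSO rep 1 or either 4C DMSO replicate. Ccnb3 lost its call without 2C DMSO rep 2 or 4C DMSO rep 1. With only the 4 libraries compared, Ccnb3 lost it too.

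The H3.3K4M transgene was compared with the H3.3WT transgene in growing oocytes. The endogenous H3.3 genes H3f3a (0.36 ± 0.18, edgeR adjusted p = 0.184) and H3f3b (0.15 ± 0.20, adjusted p = 0.646) were not called; both groups carry a transgene and counts do not separate the alleles, so these values check no label. Lower with H3.3K4M were Mbd3l2, a relative of the repressor subunit MBD3 (-6.72 ± 0.37, 0.104 ± 0.0900 against 12.6 ± 0.410 CPM), the semaphorin receptor Nrp1 (-5.80), the 2-cell gene Zscan4d (-5.30), the oocyte-specific Oog4 (-4.69 ± 0.23, 59.3 ± 12.8 against 1528 ± 91.4 CPM), Cyp19a1, the aromatase of oestrogen synthesis (-3.15), and the meiotic cyclin Ccnb3 (-2.94). Higher were the cytokine receptor gene Il11ra1 (3.96 ± 0.29), the mucus protein Fcgbp (2.88, 286 ± 8.25 against 39.0 ± 5.98 CPM), the germ-cell factor Sohlh1 (2.41), the keratin Krt8 (2.53), inhibin alpha (Inha, 1.99) and heme oxygenase Hmox1 (1.88). All of these calls had an edgeR adjusted p of at most 0.00494. Oog4 lies on chromosome 4, 143437164 to 143450324, and Mbd3l2 on chromosome 9, 18430654 to 18446316 (mm10). The zona gene Zp3 (0.13 ± 0.20, adjusted p = 0.709) and the oocyte factor Nobox (0.43 ± 0.23, adjusted p = 0.198) were not called.

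**Figure D2:**
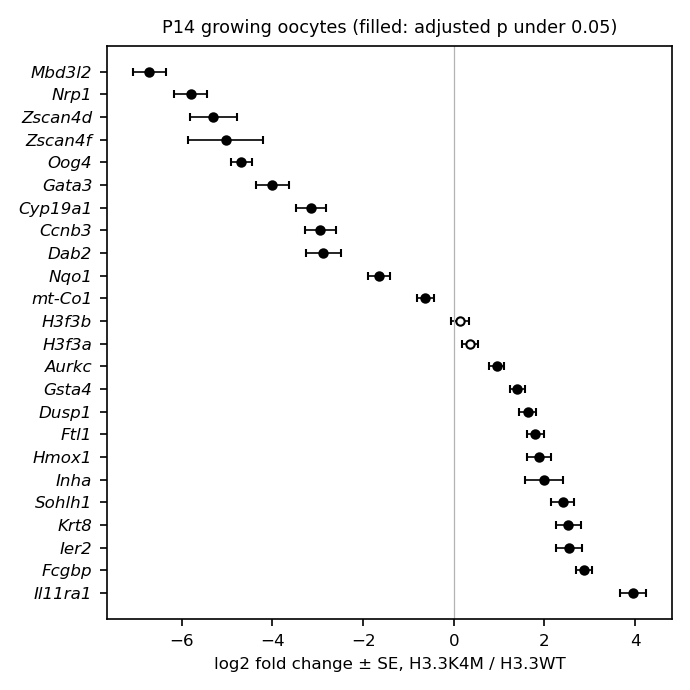
Log2 fold change (horizontal axis) of 24 named genes in growing oocytes with H3.3K4M against H3.3WT, n = 2 libraries per group, bars ± standard error. Filled points have an edgeR adjusted p under 0.05, and open points, H3f3a and H3f3b among them, do not; Mbd3l2 is lowest at -6.72 and Il11ra1 highest at 3.96.

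In all, 3444 of 15386 genes differed between the transgenes, 1329 higher and 2115 lower with H3.3K4M; at least 2-fold in 2232. Some immediate-early genes, which answer signalling within minutes, were higher, among them Ier2 (2.54) and the phosphatase Dusp1 (1.63): 9 of the 29 tested were higher (9 higher and 0 lower over the list alone). Camera gave p = 0.00365, and 0.729 with an estimated correlation. Among the 2-cell-stage transient genes, 8 of the 19 tested were lower and 1 (AU022751) higher (2 higher and 9 lower over the list alone). Camera gave p = 0.00365, and 0.838 with an estimated correlation. Of the trophectoderm and primitive-endoderm genes, 7 of the 15 tested were lower and 2 (Krt8 and Cldn4) higher (3 higher and 8 lower over the list alone), with camera adjusted p = 0.0213 and 0.729 with an estimated correlation. Some mitochondrial genome transcripts were lower, including the ribosomal RNA mt-Rnr1 (-1.27): 7 of the 15 tested were lower (0 higher and 9 lower over the list alone). Camera gave p = 0.0135, and 0.838 with an estimated correlation. Of the oocyte and maternal-effect genes, 19 of the 70 tested were lower and 8 higher (9 higher and 20 lower over the list alone), with camera adjusted p = 0.211. Among the oxidative-stress genes, ferritin light chain Ftl1 (1.80) and the glutathione transferase Gsta4 (1.40) rose and the quinone reductase Nqo1 fell (-1.64): 4 (Hmox1, Ftl1, Gsta4 and Fth1) of the 18 tested were higher and 2 (Nqo1 and Slc7a11) lower (6 higher and 2 lower over the list alone), with camera adjusted p = 0.0672. Of the H3K4 methylation enzymes and H3.3 genes, 1 (Atrx) of the 32 tested was lower (0 higher and 1 lower over the list alone), with camera adjusted p = 0.684. Most repeats called were lower: 231 of 791 subfamilies fell and 25 rose, with IAPEY5_LTR at -3.13, ORR1A0 at -1.07 and MERVL-int at -1.06 (11.4 ± 1.39 against 23.6 ± 1.41 CPM), against MURVY-int at 3.68 and MuRRS4-int at 1.25. Of the LTR subfamilies 149 of 488 were lower, and of the LINE subfamilies 50 of 130. Repeats as a share of all counts went the other way, 33.1% and 33.1% with H3.3K4M against 30.1% and 31.9%. The count of genes was 2171 without P14 H3.3WT rep 1 and the count of repeats 128 without P14 H3.3WT rep 1 and 159 without P14 H3.3WT rep 2. Fth1 lost its call without H3.3K4M rep 1 or either H3.3WT replicate. Slc7a11 lost its call without H3.3K4M rep 1 or H3.3WT rep 1. Atrx and Cldn4 lost their calls without H3.3WT rep 1.

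MII oocytes of 12-month females were compared with those of 8-week females. Lower in the older oocytes were the urea transporter Slc14a1 (at least 495-fold, 0 counts at 12 months), the ribosome assembly gene Rrs1 (at least 352-fold, also at 0), the ribosomal-protein retrogene Rpl37rt (-9.90 ± 0.43, 0.273 ± 0.000457 against 265 ± 66.9 CPM) and the immune receptor ligand Cd200 (-7.01). Higher were the receptor phosphatase Ptpro (5.97 ± 0.51, 114 ± 8.12 against 1.82 ± 1.05 CPM), the vomeronasal receptor gene Vmn1r91 (7.20) and the mitochondrial fission regulator Mtfr2 (5.57), with an edgeR adjusted p of at most 0.0329 over the genes named. The LTR subfamily RLTR12A was lower (-4.97 ± 0.43, 1.62 ± 0.600 against 50.9 ± 10.8 CPM), and RMER17D2 (2.42) and MER96 (3.56) were the 2 subfamilies called higher. In all, 121 of 15083 genes (41 higher, 80 lower) and 9 repeat subfamilies differed. No gene list was called, the lowest adjusted p being that of mitochondrial genome transcripts (camera adjusted p = 0.269), of which none of the 15 tested passed the edgeR test (0 higher and 0 lower at an unadjusted p under 0.05, 0 by DESeq2, and 0 higher and 0 lower over the list alone). Of the oocyte and maternal-effect genes, 1 (Ddx4) of the 69 tested was higher (1 higher and 1 lower over the list alone), with camera adjusted p = 0.867. Cumulus-cell markers were uneven between replicates. Gja1 stood at 32.7 and 0.1 CPM in the 8-week libraries and at 23.5 and 9.8 CPM in the 12-month ones. The fit across stages without replicates 1 kept 1 library per age, with Gja1 in MII 12m rep 2, so it cannot exclude cumulus RNA. The count was 1105 without MII 8w rep 1, 1074 without MII 8w rep 2, 44 without MII 12m rep 1 and 0 without MII 12m rep 2; every gene and subfamily named here lost its call without MII 12m rep 2, and Ddx4 and the named subfamilies also without MII 12m rep 1.

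The 2-cell embryos of 12-month females were compared with vehicle 2-cell embryos of 6-to-8-week females. The older group is labelled as untreated, so age and vehicle change together. Lower were the lymphocyte receptor gene Btla (at least 493-fold, 0 counts), the lens filament gene Bfsp1 (-8.86 ± 1.10) and Cd200 (-7.16). Higher were Ptpro (8.03 ± 1.07, 116 ± 20.8 against 0.436 ± 0.372 CPM), the germ-line RNA helicase Ddx4 (3.70), Obox2 (3.59), the leptin-receptor overlapping gene Leprot (5.69) and Dph6, an enzyme of diphthamide synthesis (5.80); the edgeR adjusted p was at most 0.0187 for these genes. Btla (chromosome 16, 45224315 to 45257670) and Cd200 (chromosome 16, 45382135 to 45409053) lie close together in mm10, and Ptpro on chromosome 6, 137252319 to 137463233. In all, 272 of 22391 genes differed (105 higher, 167 lower), and RLTR12A was the only repeat subfamily called (-2.96 ± 0.36, adjusted p = 0.00351); MERVL-int was at -0.42 ± 0.49 (adjusted p = 0.851). Of the mitochondrial genome transcripts, 4 (mt-Nd4l, mt-Nd1, mt-Nd5 and mt-Nd2) of the 15 tested were higher (14 higher and 0 lower over the list alone). Camera gave p = 7.4e-16, and 0.400 with an estimated correlation. They took 9.65% and 6.51% of gene counts in the older group and 4.13% and 3.18% in the vehicle group. Of the oocyte and maternal-effect genes, 2 (Ddx4 and Obox2) of the 69 tested were higher (5 higher and 1 lower over the list alone). Camera gave p = 9.9e-07, and 0.400 with an estimated correlation. The count was 86 without 2C 12m rep 1, 109 without 2C 12m rep 2 and 148 without 2C DMSO rep 1. mt-Nd2 lost its call without 2C 12m rep 1 or either 2C DMSO replicate, and with DESeq2 size factors or with gene-only library sizes. Btla lost its call without either 2C 12m replicate or 2C DMSO rep 1. mt-Nd1 and mt-Nd5 lost their calls without 2C 12m rep 1 or either 2C DMSO replicate. mt-Nd4l lost its call without 2C 12m rep 1 or 2C DMSO rep 2. Ptpro lost its call without either 2C 12m replicate. RLTR12A lost its call without 2C 12m rep 2. With only the 4 libraries compared, Btla, RLTR12A, mt-Nd1, mt-Nd2, mt-Nd4l and mt-Nd5 lost theirs too.

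Genes called in both 12-month comparisons moved the same way in all 61 cases, 13 higher and 48 lower, where independent lists would share 0.282 and 0.779. The older and younger oocytes and embryos are separate libraries, with no control in common. Ddx4 was at 3.54 in oocytes and 3.70 in embryos, Cd200 at -7.01 and -7.16, and Ptpro at 5.97 and 8.03. Across the 6674 genes compared the fold changes correlated with r = 0.668; genes are not independent replicates. The test of the difference between the stages called 4 genes, named after their values were seen: Rpl37rt (5.01), Cwc22 (-4.82), B020011L13Rik (-5.18) and, also with a negative difference, Ankrd10. Without MII 12m rep 2 no gene was shared, because the oocyte comparison then called 0 genes by edgeR; the shared genes numbered 129 without MII 8w rep 1, 137 without MII 8w rep 2, 33 without MII 12m rep 1, 39 without 2C 12m rep 1 and 38 without 2C 12m rep 2.

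**Figure D3:**
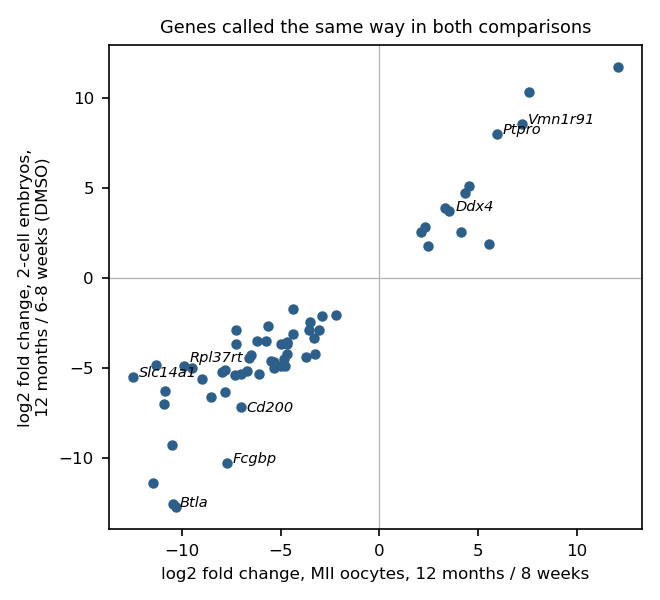
Log2 fold change of the 61 genes called in both 12-month comparisons, in MII oocytes (12 months against 8 weeks, horizontal axis) and in 2-cell embryos (12 months against 6 to 8 weeks, vertical axis). Each point is a gene from n = 2 libraries per group; 13 lie above 0 and 48 below 0 on both axes. Values of genes at 0 counts in a group, such as Slc14a1 and Btla, are fitted and not bounds.

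With aphidicolin at the 2-cell stage, the genes called lower included 2-cell-stage genes: Zscan4f (-4.48 ± 0.54), Zscan4b (-4.35), Zscan4d (-3.42), the POZ-domain gene Tdpoz3 (-4.41) and BB287469 (-4.23). AA414992 (-4.36) and the RNA-processing kinase Clp1 (-4.11) were lower too; the edgeR adjusted p was at most 0.0443. MERVL-int fell from 17834 ± 6063 to 1715 ± 983 CPM (-3.38 ± 0.54, adjusted p = 0.0278) and MT2_Mm was lower too (-2.80); they were the 2 repeats called. No label pairs the 2-cell libraries, but same-numbered libraries of the drug and vehicle groups deviated together, which the main fit leaves out. With the replicate number as a block 5 subfamilies were lower, the others being B2_Mm2, ERVB4_2-LTR_MM and MERVL_2A-int. In all, 43 genes were lower and 2 higher, Mis18a, a centromere factor (2.11), and Gm813 (2.12), of 22391 tested; with the block 101 were lower and 16 higher. Of the 2-cell-stage transient genes, 12 of the 47 tested were lower (1 higher and 34 lower over the list alone). Camera gave p = 2.1e-49, and 0.0211 with an estimated correlation. With the block 18 were lower and the latter was 0.102. Of the ribosomal proteins, none of the 79 tested passed the edgeR test (3 higher and 34 lower at an unadjusted p under 0.05, 13 by DESeq2, and 1 higher and 24 lower over the list alone). Camera gave p = 7.4e-13, and 0.405 with an estimated correlation. With the block 2, Rpl13 and Rps27a, were lower (2 higher and 34 lower over the list alone). Zfp352 (-3.32 ± 0.86, adjusted p = 0.184) and Cdkn1a, a p53 target (-1.43 ± 0.56, adjusted p = 0.417), were not called. The count was 5 without 2C APH rep 1, 148 without 2C APH rep 2 and 18 without 2C DMSO rep 1, DESeq2 called 521, and with only the 4 aphidicolin and vehicle libraries edgeR called none of the named features and 0 genes (2293 at an unadjusted p under 0.05 in the full fit). MERVL-int, MT2_Mm, Zscan4d and Zscan4f lost their calls without 2C APH rep 1. Tdpoz3 lost its call without either 2C APH replicate or 2C DMSO rep 1. AA414992, Clp1, Gm813 and Zscan4b lost their calls without 2C APH rep 1 or 2C DMSO rep 1. Mis18a lost its call without 2C APH rep 1 or either 2C DMSO replicate.

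Cycloheximide at the 2-cell stage lowered most 2-cell-stage genes. The initiation-factor-like genes Gm2016 (at least 4493-fold lower) and BB287469 (at least 2743.5-fold), the PRAME-family gene Pramef25 (at least 756-fold), Tdpoz3 (at least 559-fold), the deubiquitinase gene Usp17lc (at least 510.4-fold) and, outside the 2-cell-stage list, AA414992 (at least 594-fold) and Mycn (at least 199.9-fold) were at 0 counts in both libraries. Zscan4b (-7.36), Zscan4d (-6.29, 4.06 ± 1.28 against 319 ± 148 CPM) and Myc (-5.52) were lower. Many maternal transcripts were higher than in vehicle embryos: H1foo (5.38 ± 0.73, 15887 ± 3205 against 381 ± 16.6 CPM), the maintenance DNA methyltransferase Dnmt1 (4.48), Obox2 (4.19) and Mos (4.19). These calls had an edgeR adjusted p of at most 0.00779. In all, 5367 of 22391 genes differed, 2466 higher and 2901 lower; with only the 4 libraries compared, 3359 did. Within the 2-cell-stage transient genes, 37 of the 47 tested were lower and 3 (Sp110, AU022751 and Rnf114) higher (3 higher and 38 lower over the list alone). Camera gave p = 3.3e-36, and 0.106 with an estimated correlation. Of the oocyte and maternal-effect genes, 35 of the 69 tested were higher and 6 lower (39 higher and 6 lower over the list alone). Camera gave p = 1.1e-10, and 0.108 with an estimated correlation. Many mitosis and spindle genes such as Fbxo5, an inhibitor of the anaphase-promoting complex (3.51), and Bub1b (3.46) were higher: 24 of the 47 tested were higher and 1 (Cdc25c) lower (25 higher and 2 lower over the list alone). Camera gave p = 9.6e-10, and 0.155 with an estimated correlation. With the replicate block 2 were lower, Cdc25c and Birc5. Of the proteasome subunits, 13 of the 34 tested were higher and 2 (Psmb3 and Psmb2) lower (13 higher and 5 lower over the list alone), with camera adjusted p = 0.00232 and 0.515 with an estimated correlation; with the block 3 were lower, Psma3 being the other. Of the replication and S-phase genes, 18 of the 52 tested were higher and 6 lower (23 higher and 7 lower over the list alone), with camera adjusted p = 0.00248 and 0.515 with an estimated correlation. Psmb2 lost its call without 2C CHX rep 1 or 2C DMSO rep 2. Psmb3 lost its call without 2C CHX rep 1. Rnf114 lost its call without 2C CHX rep 2 or 2C DMSO rep 2. Cdc25c lost its call without either 2C DMSO replicate. With only the 4 libraries compared, Cdc25c, Psmb2 and Rnf114 lost theirs too.

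Many repeats were lower in the cycloheximide-treated 2-cell embryos as well. MERVL-int (-9.12, 32.2 ± 2.79 against 17834 ± 6063 CPM) and MT2_Mm (-5.36, 226 ± 45.2 against 9289 ± 409.6 CPM) fell, with edgeR adjusted p = 2.7e-05 and 0.000140. GSAT_MM (-6.37), L1Md_F2 (-2.88), L1Md_T (-1.71) and IAPEz-int (-2.62) fell as well, while MER91A (2.62) and BGLII_C (2.51) rose. Of 1016 subfamilies 514 were lower and 17 higher: 99 of 149 LINE, 302 of 606 LTR and 25 of 35 SINE subfamilies were lower. 

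MG132 at the 2-cell stage lowered most 2-cell-stage genes too. Tdpoz3 (at least 607-fold), the homeobox gene Obox6 (at least 519.9-fold), Tdpoz4 (at least 365-fold) and, outside that list, AA414992 (at least 645-fold), Cyp26a1 (at least 475-fold) and Myc (at least 172-fold) were lower, at 0 counts in both libraries; Zfp352 (-9.17) and Zscan4d (-4.35) also fell. Higher were the mediator subunit Med17 (5.17 ± 0.53), the splicing kinase Clk1 (4.06), the poly(A)-binding protein gene Pabpn1l (4.01), Obox2 (3.77), Dnmt1 (3.41) and the proteasome subunits Psmd6 (2.92) and Psma7 (2.80), all genes named having an edgeR adjusted p of at most 0.00623. In all, 2188 genes differed, 1141 higher and 1047 lower. Of the 2-cell-stage transient genes, 37 of the 47 tested were lower and 2 (Arg2 and Rnf114) higher (2 higher and 40 lower over the list alone). Camera gave p = 8.4e-56, and 0.0318 with an estimated correlation. With the replicate block the latter was 0.158. Of the oocyte and maternal-effect genes, 26 of the 69 tested were higher and 3 (Omt2b, Omt2a and Tcl1b1) lower (34 higher and 6 lower over the list alone). Camera gave p = 3.1e-10, and 0.0996 with an estimated correlation.

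Of the pluripotency genes, 7 of the 30 tested were lower and 1 (Esrrb) higher (1 higher and 7 lower over the list alone). Camera gave p = 0.00210, and 0.137 with an estimated correlation. MERVL-int (-8.14, to 63.1 ± 43.4 CPM), MT2_Mm (-5.61) and L1Md_T (-2.70) fell, among 383 subfamilies lower of 1016; 4 were higher (MamGypLTR2c, L1MEj, IAP-d-int and MTB_Mm-int, named after their values were seen). The gene count was 1025 without 2C MG132 rep 1, 969 without 2C MG132 rep 2 and 1024 without 2C DMSO rep 1, and DESeq2 called 3561. MTB_Mm-int lost its call without either 2C MG132 replicate or 2C DMSO rep 1, and with DESeq2 size factors. L1MEj lost its call whichever library was left out, and with DESeq2 size factors or without the low-count filter. Rnf114 lost its call whichever library was left out, and with DESeq2 size factors. IAP-d-int lost its call without either 2C MG132 replicate or 2C DMSO rep 1. MamGypLTR2c and Tcl1b1 lost their calls whichever library was left out. Omt2a lost its call without either 2C MG132 replicate or 2C DMSO rep 2. Arg2 and Esrrb lost their calls without 2C MG132 rep 2 or 2C DMSO rep 1. Omt2b lost its call without 2C MG132 rep 2. With only the 4 libraries compared, IAP-d-int, L1MEj and MTB_Mm-int lost theirs too.

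To set the 3 drugs against genome activation, a zygotic set of 1708 genes at least 4-fold higher in 12-month 2-cell embryos than in 12-month oocytes, and a maternal set of 1020 genes at least 4-fold lower, were drawn from libraries outside the drug and vehicle groups. Cycloheximide lowered 850 zygotic genes (49.8%), MG132 599 (35.1%) and aphidicolin 37 (2.17%), with camera p = 1.2e-30, 2.9e-34 and 5.8e-18, and p = 0.00777, 0.00369 and 0.0155 with an estimated correlation (0.0663 for aphidicolin with the 2-fold set); with the replicate block aphidicolin lowered 75 (4.39%). Of the 991 maternal genes tested, 430 (43.4%) were higher with cycloheximide and 314 (31.7%) with MG132 (p = 0.00425 and 0.00195 with an estimated correlation). Of the genes lowered by aphidicolin, 42 were also lower with MG132 and 41 with cycloheximide (with the block 96 and 92). All share the vehicle libraries: fold changes with aphidicolin correlated with r = 0.799 and 0.604 with those of MG132 and cycloheximide, against 0.492 and 0.490 for simulated unchanged groups, and 77.8% and 60.9% of genes had the same sign, against 66.4% and 66.5%. Cycloheximide and MG132 shared 869 higher and 862 lower genes (126 and 136 if independent), and 23 moved oppositely (44 with the block). Their fold changes correlated across genes with r = 0.800, against 0.495 for 10 pairs of unchanged groups simulated with their vehicle libraries. The covariance was 2.86 against 0.139. Part of the excess may come from the real shared controls, and the simulations leave the pairing out. The drugs also differed: cycloheximide left H1foo (3.43 ± 0.67, log2) and Mos (2.76 ± 0.60) higher and the respiratory gene Ndufa4 lower (-3.11 ± 0.33) than MG132, among 2128 genes, and MERVL-int was higher with aphidicolin than with cycloheximide (5.74 ± 0.61) or MG132 (4.76 ± 0.58), with 4056 and 367 genes differing.

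**Figure D4:**
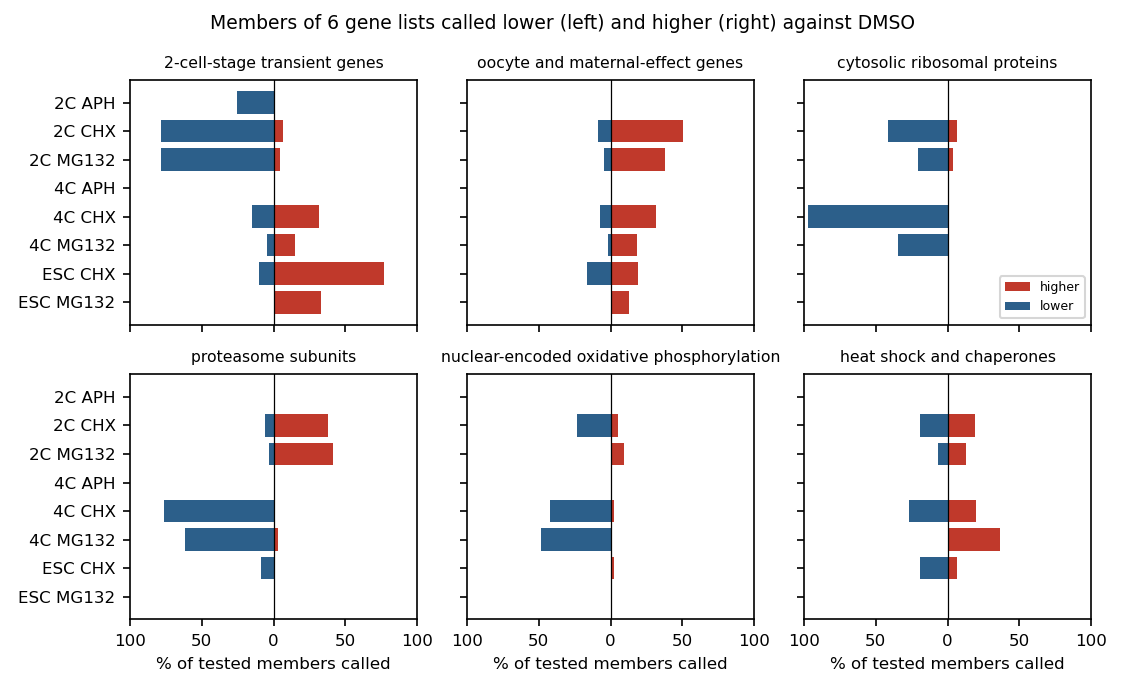
Percent of tested members of 6 gene lists called lower (left of 0) or higher (right of 0) by edgeR at an adjusted p under 0.05, in the 8 drug comparisons (n = 2 libraries per group). The 2-cell-stage genes lie mostly on the lower side with cycloheximide and MG132 at 2 cells and on the higher side in stem cells, and called members of ribosomal proteins, proteasome subunits and oxidative phosphorylation lie mostly on the lower side with both drugs at 4 cells.

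In the fit of the 4-cell libraries aphidicolin changed no gene past the edgeR test (1846 genes at an unadjusted p under 0.05, and 224 by DESeq2), while the fit of all 18 embryo libraries called 57 higher and 15 lower. Cdkn1a, a p53 target, stood at 147 ± 54.7 against 28.4 ± 13.7 CPM (2.37 ± 0.53, edgeR adjusted p = 0.519) and Myc at 2.27 ± 0.82, neither of them called. MERVL-int (0.04 ± 0.46, a sign that turned with other scalings) and IAPEz-int (-1.05 ± 0.39) were not called either, and edgeR called 0 repeat subfamilies (77 at an unadjusted p under 0.05, 11 by DESeq2). Of the p53 targets and DNA damage genes, none of the 37 tested passed the edgeR test (10 higher and 0 lower at an unadjusted p under 0.05, 7 by DESeq2, and 7 higher and 0 lower over the list alone); camera placed the list higher. Camera gave p = 9.2e-08, and 0.0635 with an estimated correlation. Of the replication-dependent histones, none of the 58 tested passed the edgeR test (0 higher and 11 lower at an unadjusted p under 0.05, 2 by DESeq2, and 0 higher and 1 lower over the list alone); camera placed the list lower. Camera gave p = 8.3e-09, and 0.234 with an estimated correlation. The difference between the stages called 0 genes by edgeR (2892 at an unadjusted p under 0.05, 538 by DESeq2), so the 2-cell and 4-cell responses to aphidicolin are not shown to differ gene by gene.

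Cycloheximide at the 4-cell stage lowered most ribosomal protein and proteasome genes. The ribosomal proteins Rpl36a (-3.85 ± 0.47), Rpl5 (-3.53) and Rps23 (-3.59), the proteasome subunits Psmd7 (-3.78) and Psma7 (-3.63), the respiratory-chain genes Cox7c (-3.87) and Ndufa5 (-3.65), the chaperone Hspa8 (-3.77), the nucleolar protein Npm1 (-2.69) and the PRAME-family genes Pramel6 (-6.33) and Pramel7 (-3.94) fell. Higher were the p53 targets Cdkn1a (2.62 ± 0.53) and Btg2 (4.84), Gadd45g (7.11), Klf6 (7.41), the heat-shock genes Hspa1a (3.75) and Hspa1b (4.41), the germ-cell genes Sohlh1 (8.25) and Dazl (3.76) and, from 0 counts, Gata2 (at least 173-fold higher) and Crabp1 (at least 609-fold). The edgeR adjusted p was at most 0.0107 over these genes. Of the ribosomal proteins, 77 of the 79 tested were lower (0 higher and 79 lower over the list alone). Camera gave p = 2.1e-49, and 0.246 with an estimated correlation. For ribosome biogenesis, 42 of the 60 tested were lower (0 higher and 48 lower over the list alone). Camera gave p = 3.7e-22, and 0.246 with an estimated correlation. For proteasome subunits, 26 of the 34 tested were lower (1 higher and 26 lower over the list alone), with camera adjusted p = 7.9e-16 and 0.0971 with an estimated correlation, and for oxidative phosphorylation, 32 of the 76 tested were lower and 2 (Ndufv1 and Ndufb9) higher (4 higher and 37 lower over the list alone). Camera gave p = 8.3e-09, and 0.282 with an estimated correlation. Among the 2-cell-stage transient genes, 15 of the 47 tested were higher and 7 lower (17 higher and 7 lower over the list alone), with camera adjusted p = 0.0897. RLTR45-int (-5.39 ± 0.34, 53.8 ± 9.22 against 2259.5 ± 120.2 CPM) and ERVB4_2-I_MM-int (-3.71) fell and RLTR9A3A rose (3.32); MERVL-int was at 0.65 ± 0.46 (adjusted p = 0.523). Mitochondrial transcripts took 23.1% and 21.7% of gene counts (17.2% and 15.4% with MG132) against 14.6% and 11.4% with vehicle. In all, 4290 genes differed, 1975 higher and 2315 lower, around a median of 0.44; the count was 2439 without 4C CHX rep 1, 2602 without 4C CHX rep 2, 2511 without 4C DMSO rep 1 and 2335 without 4C DMSO rep 2, and DESeq2 called 6584. Ndufb9 and Ndufv1 lost their calls whichever library was left out, and without the low-count filter.

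MG132 at the 4-cell stage raised some heat-shock genes: Hspa1b (7.20 ± 0.86), Hspa1a (6.50 ± 0.51, 48.8 ± 0.764 against 0.539 ± 0.217 CPM), the co-chaperone Dnajb1 (4.26) and the mitochondrial chaperonin gene Hspe1 (3.53), with the immediate-early factors Egr1 (5.85) and Klf6 (6.12). Lower were the pluripotency factor Prdm14 (at least 82.4-fold) and the histone Hist1h1b (at least 251-fold), both at 0 counts, Zfp42 (-3.83), the respiratory-chain genes Ndufa8 (-5.08) and Sdhb (-4.07), the proteasome subunits Psma7 (-3.47) and Psmb3 (-3.04) and the ribosomal protein Rpl3 (-2.96). The edgeR adjusted p was at most 0.0198. Of the heat shock and chaperone genes, 11 of the 30 tested were higher (16 higher and 2 lower over the list alone). Camera gave p = 1.5e-06, and 0.237 with an estimated correlation. For oxidative phosphorylation, 37 of the 76 tested were lower (0 higher and 51 lower over the list alone). Camera gave p = 1.1e-25, and 0.197 with an estimated correlation. For ribosomal proteins, 27 of the 79 tested were lower (0 higher and 56 lower over the list alone), with camera adjusted p = 6.5e-22 and 0.296 with an estimated correlation, and for proteasome subunits, 21 of the 34 tested were lower and 1 (Psme4) higher (1 higher and 24 lower over the list alone). Camera gave p = 6.8e-17, and 0.104 with an estimated correlation. RLTR45-int (-4.07) and ERVB4_2-I_MM-int (-2.86) fell; MusHAL1 (1.79) was the 1 subfamily called higher. In all, 1663 genes differed, 689 higher and 974 lower; the count was 810 without 4C MG132 rep 1, 1050 without 4C MG132 rep 2, 767 without 4C DMSO rep 1 and 581 without 4C DMSO rep 2, and DESeq2 called 3843. MusHAL1 lost its call without 4C MG132 rep 1 or either 4C DMSO replicate. Psme4 lost its call whichever library was left out. Cycloheximide and MG132 shared 482 higher and 598 lower genes at this stage (60.4 and 100.1 if independent), with r = 0.623 across genes against 0.497 for simulated unchanged groups and a covariance of 1.86 against 0.177. They differed at 2273 genes: Atf3 (6.98 ± 1.01) and Cdkn1a (2.61 ± 0.53) were higher with cycloheximide, Hspa1a (-2.74 ± 0.42) and Rpl5 (-1.16 ± 0.23) higher with MG132.

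The same drug gave different responses at the 2 embryo stages, by a test of the difference itself. For cycloheximide, 5688 genes differed (3879 with a higher change at 4 cells and 1809 with a lower one, around a median of 1.25): Zscan4d by 8.68 ± 0.89 and Psma7 by -7.99 ± 0.58 (log2 difference of the changes, edgeR adjusted p at most 1.2e-05), and MERVL-int by 9.81 ± 0.91. Of the 2-cell-stage transient genes 35 of the 47 tested were higher and 2 lower at 4 cells (camera adjusted p = 1.2e-22 and 0.0637 with an estimated correlation), and of the proteasome subunits 19 of the 34 tested were lower (camera adjusted p = 2.7e-17 and 0.0215 with an estimated correlation). For MG132, 3051 genes differed, Zscan4d by 5.62 ± 0.83 and Psma7 by -6.27 ± 0.56 among them, and MERVL-int by 9.49 ± 0.90; of the 2-cell-stage transient genes 36 of the 47 tested were higher (camera adjusted p = 2.7e-35 and 0.0270 with an estimated correlation). For cycloheximide the count of genes was 3713 without 4C DMSO rep 2. For MG132 the count of genes was 1940 without 2C MG132 rep 1, 1603 without 2C MG132 rep 2, 1859 without 2C DMSO rep 1 and 1972 without 4C DMSO rep 2. Changes with cycloheximide at 2 and 4 cells correlated with r = -0.0503 across genes; 251 genes were higher at both stages and 473 lower (244 and 312 if independent), and 725 were called in opposite directions. At 4 cells, the changes with cycloheximide and MG132 ran along the difference between vehicle 2-cell and 4-cell embryos, taken as 2-cell minus 4-cell, in the fit of all 18 embryo libraries (27201 genes). Of 2830 genes higher and 2063 lower with cycloheximide in that fit, 2100 and 1398 shared it (626 and 352 if independent), and of 1326 and 918 with MG132, 1161 and 526 (293 and 157). For aphidicolin, all 57 higher genes of that fit shared it (12.6 if independent), but 0 lower ones did, and 13 moved oppositely. These pairs share the vehicle 4-cell libraries; the covariance was 5.35 against 0.238 simulated for cycloheximide, 3.92 against 0.219 for MG132 and 1.62 against 0.220 for aphidicolin, whose r of 0.423 lay under the simulated 0.502, and part of the excess may come from those libraries.

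In stem cells, cycloheximide raised most 2-cell-stage genes. Duxf3, the Dux gene whose product activates MERVL (3.98 ± 0.42), Zscan4f (3.12 ± 0.15, 21.6 ± 0.114 against 2.49 ± 0.328 CPM), Zscan4c (2.79), Tmem92 (3.61), Usp17lb (3.70) and Usp17ld (3.82) were higher, as were the Notch ligand Dll1 (3.44), the linker histone Hist1h1a (2.70), the stress factors Atf3 (1.64) and Herpud1 (1.48), the p53 target Pmaip1 (1.41) and the immediate-early gene Fos (1.42). Lower were the interferon-induced Usp18 (-3.78 ± 0.22) and Isg15 (-3.33), the Nodal antagonist Lefty2 (-2.48), the epiblast factor Otx2 (-1.78), Mycn (-1.70), the collagens Col6a1 (-1.94) and Col1a2 (-1.56), the ribosome biogenesis gene Nop16 (-1.07) and the origin-licensing factor Cdc6 (-0.86). The edgeR adjusted p was at most 0.00165. Nanog (0.15 ± 0.15, adjusted p = 0.500) and Pou5f1 (0.21 ± 0.17, adjusted p = 0.398) were not called. MERVL-int rose from 299 ± 43.7 to 1833 ± 40.3 CPM (2.62 ± 0.15, adjusted p = 0.000146) and MT2_Mm by 2.02, 2 of the 5 subfamilies called higher, with LTR16D, MER105 and ERVL-E-int, named after their values were seen; ERVB4_2-I_MM-int (-1.82) and RLTR45-int (-1.62) were lower.

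Cycloheximide changed 5042 genes in stem cells (2546 higher, 2496 lower), 1958 at least 2-fold. Within the 2-cell-stage transient genes, 30 of the 39 tested were higher and 4 (Pramel6, Pramel7, Obox6 and Ube2q1) lower (30 higher and 4 lower over the list alone). Camera gave p = 8.2e-36, and 0.0148 with an estimated correlation. Of the replication-dependent histones, in poly(A) RNA only, 31 of the 53 tested were higher (41 higher and 0 lower over the list alone). Camera gave p = 1.7e-15, and 0.177 with an estimated correlation. Of the p53 targets, 21 of the 38 tested were higher and 2 (Fbxo32 and Tigar) lower (25 higher and 2 lower over the list alone). Camera gave p = 1.5e-09, and 0.116 with an estimated correlation. Of the integrated stress and unfolded-protein response genes, 13 of the 39 tested were higher and 6 lower (17 higher and 7 lower over the list alone). Camera gave p = 0.00559, and 0.387 with an estimated correlation. For ribosome biogenesis, 24 of the 60 tested were lower (0 higher and 28 lower over the list alone). Camera gave p = 1.7e-06, and 0.387 with an estimated correlation. The count was 1093 without ESC CHX rep 1, 1146 without ESC CHX rep 2, 1071 without ESC DMSO rep 1 and 1254 without ESC DMSO rep 2; with only the 4 libraries compared it was 10640. Obox6 lost its call whichever library was left out, and without the low-count filter or by DESeq2. Fbxo32 and LTR16D lost their calls whichever library was left out, and by DESeq2. Tigar lost its call without either ESC CHX replicate or ESC DMSO rep 1. ERVL-E-int, MER105 and Ube2q1 lost their calls whichever library was left out.

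MG132 in stem cells changed fewer genes. Lower were Usp18 (-5.79 ± 0.28, 0.204 ± 0.0942 against 11.7 ± 0.261 CPM), Isg15 (-4.23), the GTPase Irgm1 (-3.97), Ifi27 (-3.72) and the interferon regulator Irf7 (-3.21), the collagens Col6a1 (-1.45) and Col1a2 (-1.38) and the matrix proteoglycan Dcn (-1.16). Higher were BB287469 (2.63 ± 0.52), Usp17la (2.19), Zscan4d (1.52), Zscan4c (1.47), the germ-cell gene Dazl (1.06), Fos (1.51) and Pmaip1 (1.04), with an edgeR adjusted p of at most 0.0421 for the genes named. MERVL-int was at 0.93 ± 0.14 (adjusted p = 0.0926) and Hspa1a at 0.09 ± 0.15 (adjusted p = 0.765); edgeR called 0 repeat subfamilies (16 by DESeq2, 189 at an unadjusted p under 0.05). Among the 2-cell-stage transient genes, 13 of the 39 tested were higher (19 higher and 0 lower over the list alone). Camera gave p = 3.8e-14, and 0.0594 with an estimated correlation. Of the heat shock and chaperone genes, none of the 31 tested passed the edgeR test (1 higher and 2 lower at an unadjusted p under 0.05, 1 by DESeq2, and 0 higher and 0 lower over the list alone), with camera adjusted p = 0.375. Of the stroma and fibroblast feeder markers, 8 of the 17 tested were lower (0 higher and 8 lower over the list alone) for MG132, with camera adjusted p = 8.5e-08 and 0.386 with an estimated correlation, and 8 of the 17 tested were lower and 1 (Dcn) higher (1 higher and 8 lower over the list alone) for cycloheximide. Camera gave p = 0.000269, and 0.409 with an estimated correlation. With cycloheximide, Dcn lost its call whichever library was left out, and by DESeq2. The count was 9037 without ESC MG132 rep 1, 4813 without ESC MG132 rep 2, 9 without ESC DMSO rep 1 and 8 without ESC DMSO rep 2; without either vehicle replicate, or with only the 4 libraries compared, the calls of Usp18, Isg15, Irgm1, Ifi27 and Irf7 were kept and those of the other genes named for MG132 were not. Cycloheximide exceeded MG132 for MERVL-int (1.69 ± 0.14), Zscan4d (1.54 ± 0.14) and Herpud1 (1.45 ± 0.18), among 3267 genes that differed, and the drugs shared 283 higher and 175 lower genes (48.3 and 33.5 if independent), with r = 0.528 against 0.507 simulated and a covariance of 0.0878 against 0.0170.

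The response of 2-cell embryos was tested against that of stem cells, whose library kit differs and cancels only within each system. With cycloheximide, 4628 genes differed in their change, Zscan4f by -11.19 ± 0.73, Zscan4d by -9.36 ± 0.73, Usp17lb by -10.14 ± 0.59 and MERVL-int by -11.74 ± 0.81 (log2, 2-cell minus stem cell, edgeR adjusted p at most 6.2e-05). Of the 2-cell-stage transient genes 34 of the 47 tested were lower at 2 cells (camera adjusted p = 1.5e-33 and 0.0339 with an estimated correlation). With MG132, 1741 genes differed, BB287469 by -11.71 ± 0.74 and Zscan4d by -5.86 ± 0.68, and MERVL-int by -9.06 ± 0.76; of the 2-cell-stage transient genes 31 of the 47 tested were lower (camera adjusted p = 1.9e-41 and 0.0104 with an estimated correlation). Across genes the changes correlated with r = -0.132 for cycloheximide and -0.0315 for MG132. For cycloheximide the count of genes was 2215 without ESC CHX rep 1, 2270 without ESC CHX rep 2, 2222 without ESC DMSO rep 1 and 2188 without ESC DMSO rep 2. For MG132 the count of genes was 585 without ESC MG132 rep 1, 451 without ESC MG132 rep 2, 396 without ESC DMSO rep 1, 395 without ESC DMSO rep 2, 1007 without 2C MG132 rep 1 and 722 without 2C MG132 rep 2.

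The remaining marker lists were read for RNA of other cells, and those with at least 3 members called in a direction are given. Camera called none of them, the lowest adjusted p being 0.0775. Of the granulosa and cumulus markers in growing oocytes, 3 (Inha, Kctd14 and Hsd3b1) of the 8 tested were higher and 2 (Cyp19a1 and Fshr) lower. Kctd14 lost its call without H3.3WT rep 1, and with gene-only library sizes or by DESeq2. Fshr lost its call without H3.3K4M rep 2 or H3.3WT rep 1, and by DESeq2. Hsd3b1 lost its call without H3.3WT rep 1. Of the same markers at 2 cells, 4 (Fst, Ptgs2, Tnfaip6 and Gja1) of the 20 tested were lower and 1 (Serpine2) higher with cycloheximide, and 3 (Fst, Gja1 and Nap1l5) of the 20 tested were lower and 2 (Cyp19a1 and Serpine2) higher with MG132 (4 lower with the replicate block, with Tnfaip6). Ptgs2 lost its call without either 2C CHX replicate or 2C DMSO rep 2. Tnfaip6 lost its call whichever library was left out. With only the 4 libraries compared, Ptgs2 lost it too. With MG132, Fst and Nap1l5 lost their calls without either 2C MG132 replicate or 2C DMSO rep 1. Cyp19a1 lost its call without 2C MG132 rep 1 or 2C DMSO rep 1. From 2 to 4 cells, of the granulosa and cumulus markers 6 of the 21 tested were lower and 2 (Amhr2 and Gja1) higher, of the blood and immune markers 4 (C1qb, Lyz2, Laptm5 and Cd74) of the 13 tested were lower, and of the sperm markers 4 (Odf1, Akap4, Prm2 and Odf2) of the 10 tested were lower and 2 (Tsga8 and Ldhc) higher. Gja1 lost its call whichever library was left out, and with gene-only library sizes. Cd74 lost its call without 2C DMSO rep 1 or 4C DMSO rep 1. Ldhc lost its call without either 2C DMSO replicate or 4C DMSO rep 2. Tsga8 lost its call whichever library was left out. In stem cells with cycloheximide, of the granulosa and cumulus markers 6 of the 19 tested were higher and 1 (Ptx3) lower, and of the blood and immune markers, 3 (C1qa, C1qb and Lyz2) of the 9 tested were lower and 2 (Cd68 and Laptm5) higher. Cd68 and Laptm5 lost their calls whichever library was left out. C1qa and C1qb lost their calls without ESC CHX rep 2 or ESC DMSO rep 1.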

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

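The differences between stages and systems given here were planned, and the tests of explanations were chosen after the results were seen. The change with cycloheximide differed between 4-cell and 2-cell embryos at 5688 genes (MERVL-int by 9.81, log2), and with MG132 at 3051 (MERVL-int by 9.49). The 12-month difference was not the same in 2-cell embryos and MII oocytes at 4 genes. Between 2-cell embryos and stem cells, cycloheximide changes differed at 4628 genes (MERVL-int by -11.74) and MG132 changes at 1741 (MERVL-int by -9.06).

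With cycloheximide, MERVL-int and most 2-cell-stage genes were lower in 2-cell embryos and higher in stem cells. The tables argue against a changed library total as the whole cause of the fall at 2 cells, since a total moves all transcripts alike, while MERVL-int lay at -10.50 (log2) relative to the median of the maternal set, which was itself at 1.38. A candidate explanation of the embryo side is that treated embryos did not pass genome activation: 49.8% of the genes that rise from oocyte to 2 cells in the 12-month libraries were lower. In stem cells, slower decay of short-lived RNA stays open, because the median of the snoRNA host and nonsense-mediated-decay-sensitive transcripts was -0.13 with members called on both sides (camera adjusted p = 0.948). An effect of lost translation that depends on cell type, dose or duration stays open, untested.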

How the results depend on the processing

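Alternatives chosen after the data were seen are the stage fit without both MII replicates 1, the recount of genes shared by the 12-month comparisons, the crossed numbers, and the replicate block for sets, lists and overlaps. The 327 named features have 3513 values under the alternatives. Under other settings 2125 kept direction and side of the threshold, 67 lost the call, 9 gained one and 4 turned. With 1 library left out, 1073 kept both, 226 lost the call, 6 gained one and 3 turned. A lone library left in a group is assumed to vary like the other groups. Counts of calls and set values stayed within 1.5 times in 217 cases under other settings and moved further in 75; with 1 library left out these were 63 and 97. In simulations 8.96% of 4-fold changes were called for cycloheximide at 4 cells, 20.9% for aphidicolin at 2 cells and 98.5% for cycloheximide in stem cells. Total counts do not follow that order (28605693 to 32925454 for the first and 20721090 to 22153957 for the last), while the biological coefficient of variation does (0.717, 0.578 and 0.119), so depth is not shown to limit the embryo calls. The median of all genes shifted by -0.13 for 2C MG132 with DESeq2 size factors, -0.14 for MG132 between 2C and ESC and 0.14 for MG132 between embryo stages, and with gene-only library sizes by 0.12 and 0.22 for aphidicolin and MG132 between embryo stages.

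In this list 2C and 4C are the embryo stages, ESC the stem cells, APH aphidicolin and CHX cycloheximide; a group named alone is set against its vehicle or younger group, and the cause of each change was not tested unless stated. With the DESeq2 Wald test, the genes called became 521 (2C APH), 3561 (2C MG132), 1047 (2C 12m), 224 (4C APH), 6584 (4C CHX), 3843 (4C MG132), 1009 (MII 12m), 538 (APH between embryo stages), 4828 (MG132 between embryo stages), 223 (12m between MII and 2C) and 3098 (MG132 between 2C and ESC), and the repeat subfamilies 16 (ESC MG132), 71 (2C APH), 15 (2C 12m), 11 (4C APH), 108 (4C CHX), 44 (4C MG132) and 63 (MII 12m), and the genes shared by both 12-month comparisons 308. Without the low-count filter, the genes called became 1336 (ESC MG132), 615 (2C APH), 962 (2C 12m), 347 (4C APH), 3463 (4C MG132), 788 (MII 12m), 849 (APH between embryo stages) and 309 (12m between MII and 2C), and the repeat subfamilies 29 (ESC CHX), 35 (ESC MG132), 23 (2C APH), 7 (2C 12m), 10 (4C APH), 81 (4C CHX), 37 (4C MG132) and 56 (MII 12m), and the genes shared by both 12-month comparisons 266. With at least 5 CPM in 2 libraries, which leaves fewer genes tested, the genes called became 1463 (growing oocytes), 3106 (ESC CHX), 93 (2C APH) and 2548 (4C MG132), and the repeat subfamilies 2 (2C 12m) and 16 (4C MG132). With only the groups compared in the fit, and so fewer residual degrees of freedom, the genes called became 10640 (ESC CHX), 15 (ESC MG132), 0 (2C APH), 3359 (2C CHX), 116 (2C 12m) and 7167 (4C CHX), and the repeat subfamilies 201 (ESC CHX), 0 (2C APH), 322 (2C CHX), 0 (2C 12m), 14 (4C MG132) and 210 (2C against MII). With a 2-fold minimum, which can only remove calls, the genes called became 2232 (growing oocytes), 1958 (ESC CHX) and 268 (ESC MG132), and the repeat subfamilies 130 (growing oocytes). In the stage fit without both MII replicates 1, the genes called became 80 (MII 12m), and the repeat subfamilies 15 (MII 12m). The gene list tests of the 13 comparisons called 3 pairs of list and comparison with an estimated correlation. The percent of the maternal set called higher with aphidicolin at 2 cells was 0.0432 with a set from at least 2-fold and 0.258 with 1 from at least 8-fold, against 0.101 from 4-fold. With 1 library left out, and so fewer samples, the genes called ran over 2171 to 3783 (growing oocytes), 1071 to 1254 (ESC CHX), 8 to 9037 (ESC MG132), 5 to 148 (2C APH), 969 to 1805 (2C MG132), 86 to 183 (2C 12m), 0 to 1 (4C APH), 2335 to 2602 (4C CHX), 581 to 1050 (4C MG132), 0 to 1105 (MII 12m), 2811 to 3453 (2C against MII), 0 to 162 (APH between embryo stages), 3713 to 4536 (CHX between embryo stages), 1603 to 2583 (MG132 between embryo stages), 0 to 24 (12m between MII and 2C), 2188 to 5015 (CHX between 2C and ESC) and 395 to 2578 (MG132 between 2C and ESC). Those of repeat subfamilies ran over 128 to 227 (growing oocytes), 5 to 6 (ESC CHX), 0 to 281 (ESC MG132), 0 to 9 (2C APH), 141 to 319 (2C MG132), 0 to 1 (2C 12m), 0 to 1 (4C APH), 20 to 23 (4C CHX), 2 to 8 (4C MG132), 0 to 61 (MII 12m), 197 to 269 (2C against MII) and 145 to 233 (4C against 2C), and the shared 12-month genes over 0 to 137. H3f3b in growing oocytes, not called, was at -0.00478 without H3.3K4M replicate 1 and at 0.31 without H3.3K4M replicate 2. MERVL-int with aphidicolin at 4 cells, not called, was at -0.0139 with DESeq2 size factors and the DESeq2 Wald test, -0.0106 with gene-only library sizes, -0.71 without 4C APH replicate 2, 0.51 without 4C APH replicate 1 and -0.0339 without 4C DMSO replicate 2.

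Outside the 2-cell drug and vehicle groups, replicate numbers share only a number: the correlation of deviations of same-numbered libraries was -0.393 in growing oocytes, -0.132 in MII oocytes, 0.0459 to 0.167 in stem cells and -0.0444 to 0.121 at 4 cells, not over 0.1 for every pair. With the replicate number as a block, the genes called became 203 (ESC MG132), 117 (2C APH), 438 (2C 12m), 188 (MII 12m) and 1 (12m between MII and 2C), and the repeat subfamilies 169 (growing oocytes), 5 (2C APH) and 2 (2C 12m). With this block, the percent of the zygotic set called lower with aphidicolin was 4.39, that of the maternal set called higher 0.404, and the list tests of the 2-cell drugs with an estimated correlation numbered 0. Apart from what is printed beside them, it changed no call of a gene, subfamily or list test given for the 2-cell drugs. MERVL-int with aphidicolin at 4 cells was at -0.13 with the block, not called. With the numbers crossed, 5727 genes and 353 subfamilies were called in growing oocytes and 124 and 13 in MII oocytes.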

Other observations

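The tests and the interferon list in this part were chosen after the results were seen. Most of the interferon-stimulated genes listed, which encode antiviral proteins and their regulators, were lower in stem cells with either drug. Of 44 such genes 40 were tested; 26 were lower and 2 higher with cycloheximide, and 28 were lower with MG132 (29 lower and 2 higher, and 36 lower, adjusted over the list alone), with median log2 fold changes of -1.56 and -1.66. The antiviral genes Rtp4 (-4.35 with cycloheximide and -5.17 with MG132), Oas2 (-2.01 and -2.50) and Oasl2 (-4.66 and -4.01) fell with both, the call of Oasl2 with MG132 ending without either vehicle library. The antigen-processing genes Psmb9 (1.17) and Tap1 (1.35) were the 2 that rose with cycloheximide, Psmb9 not without ESC DMSO replicate 2 (edgeR adjusted p = 0.0534). With MG132 Psmb9 was at 0.25 and Tap1 at 0.34, not called (adjusted p = 0.436 and 0.234), though Tap1 was called without ESC MG132 replicate 2 (adjusted p = 0.00503) and B2m without replicate 1. The 28 lower genes with MG132 became 9 without ESC DMSO replicate 1 and 8 without ESC DMSO replicate 2, and the 26 with cycloheximide 16 without ESC CHX replicate 1 and 17 without ESC CHX replicate 2. Camera gave p = 8.9e-25 and 2.6e-90 at the preset correlation and p = 0.00233 and 0.000256 with an estimated correlation; since the genes were picked from these libraries, neither is independent evidence of a direction.

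Several collagens and many of these interferon-stimulated genes were thus lower with both drugs against the same vehicle cultures. One unusual vehicle library is argued against: without either vehicle library the smallest fall of Usp18 and Col1a2 was still -1.25, although the call of Col1a2 with MG132 then ended. Fewer fibroblast-like cells in the drug-treated cultures stay open: 6 of the 17 tested stroma markers, all collagens, were lower with both drugs, and no value here shows how much of the others, such as Fn1 (1427 ± 143 CPM with vehicle), the stem cells make themselves. A difference of both vehicle libraries from the treated cultures, such as an interferon response in the vehicle cultures, cannot be told apart from an effect of both drugs, because the series holds no other control of these cells; it may account for what the drugs share, but not for the difference of 2.01 in Usp18 between cycloheximide and MG132. A common effect of the drugs stays open and was not tested.

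The 61 genes that differed the same way in 12-month oocytes and embryos clustered more often than random sets. Within 1 Mb were 10 pairs (random sets of like expression: median 2, highest 11, permutation p = 0.000600). Of these 6 had different name stems (median 2, permutation p = 0.0290), Gm21411 with Zfp981, Zfp989 and Zfp534 among them. The sets ignore gene families, so a genetic difference between the females cannot be told from shared regulation or reads shared by near-identical copies. Oocyte RNA carried into the embryo cannot be told apart from new synthesis. Of the shared genes 2, Fcgbp and Gm42553, were higher in young 2-cell embryos than in young oocytes, but only relative to the library. The other 59 were not called higher. Among the shared genes 0 were in the 4 marker lists for RNA of blood, stroma, cumulus or sperm cells, but only 4 of the 71 marker genes reached 10 CPM in oocytes, so that source stays open. Age itself, and the vehicle at the 2-cell stage, stay open as well.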
